A study of Ruminiclostridium cellulolyticum with 15 samples.

How the data were processed

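RNA was sequenced from 15 cultures of Ruminiclostridium cellulolyticum H10, 3 for each of 5 groups. Per the labels' protocols, cells were separated from residual substrate by filtration and centrifugation, and cells grown on soluble cellobiose were handled for the same length of time as those grown on insoluble substrates. RNA was treated to remove DNA, and libraries were made with a total RNA kit that depletes ribosomal RNA and read on an Illumina sequencer. The labels state that the cultures were grown in triplicate.

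The authors deposited a table of raw whole-number read counts per coding sequence, with 3444 rows and 1 column per library. HTSeq 2.0.3 and DESeq2 1.34.0 are named in the submitters' processing notes, with no role or order given. The aligner, the genome build and the strand setting of the counting are not given in the sources used here, so reads from overlapping or antisense genes and from near-identical copies cannot be assigned further. The table gives a current identifier in each row and an older locus tag in 3345 rows, and 99 rows have none. It does not pair them with gene names or products, and no reference annotation was used here. Genes are therefore given by locus tag, without coordinates.

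Each column was matched to its sample through the column name given in the labels. The totals per library ran from 10714943 to 20715699 counts. CPM values are the counts of a gene scaled to these totals. Differences were tested in R 4.3.3 with edgeR 4.0.16 on the deposited counts, by a robust quasi-likelihood fit (glmQLFit, glmQLFTest) with TMM scaling and the group as the only term. All 15 libraries entered 1 fit and shared the estimate of the spread. The default filter on low counts (filterByExpr, minimum count 10) kept 3156 genes and left out 288. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are those of the fit, first group over second, and standard errors were derived from it. Fold changes of genes with a few counts in a group depend on the prior count of the fit, and for 3 of the genes named close to the detection limit the counts are given in place of a fold.

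The comparisons, their tests, the gene lists and the alternatives were fixed before the data were examined. The lists were to be tested with camera (limma 3.58.1), with the correlation between genes estimated and adjustment over the lists of a comparison. Camera sets a list against the other genes, while fry tests whether the genes of a list move, on balance, 1 way. Of the fixed lists, only the 3 defined by locus tags were used: the cip-cel cluster, the xyl-doc cluster, and cellodextrin uptake and phosphorolysis, which with 4 genes was under the minimum of 5 for a list test. The others were defined by words in product names and were not applied here. They were cellulosome components, carbohydrate-active enzymes, sugar transporters, the pentose pathway, glycolysis, fermentation, oxidative stress defence, oxidoreductases, aromatic compound enzymes, efflux, chaperones and proteases, ribosomal proteins, sporulation, flagella and chemotaxis, iron uptake, nitrogen assimilation, peptide and amino acid transport, regulators of the 2-component type, sigma factors, the cell envelope, and mobile elements. For straw end versus cellobiose and straw mid versus mix, list tests were not part of the fixed design and were computed in the same way after it.

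The genes named were those with the largest fitted change in each direction among called genes with a mean of at least 20 CPM over the compared groups and no overlap between replicates. The rule had foreseen more genes per direction. It was reduced to 2 that were higher and 2 that were lower per comparison because locus tags without product names carry little information. From the straw-raised set the first 2 by the smallest of the 3 log2 fold changes are given, under the same filters in each of the 3 comparisons. Members of the fixed clusters are named where they illustrate a count, and Ccel_0730, Ccel_0739, Ccel_1229 in straw end versus mix and in mix versus cellulose, Ccel_1231 and Ccel_2109 to Ccel_2112 were chosen for this after their values were seen.

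The alternatives were RLE size factors, total-count scaling, no filter, a filter of at least 50 counts in at least 3 libraries, DESeq2 1.42.0, a fit of the 2 groups compared, the replicate number as a block, removal of 22 genes that hold over 1% of the counts of a library, each library left out in turn, a preset correlation of 0.01 and fry for the lists, and other fold thresholds for the straw sets. The fits without straw end replicate 1 for comparisons outside that group, and for the lists, were chosen after the data were seen. The scripts were tested on simulated counts drawn with the means and library sizes of the data. For straw end versus mix, with 3153 genes, edgeR recovered 26% of genes changed 2-fold and 80% of those changed 4-fold, and 3.31% of its calls were unchanged genes. For mix versus cellulose, with 3153 genes, it recovered 32% and 78%, and 9.16% of its calls were unchanged genes, against 13.5% for DESeq2. Closing tests and figures used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.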

Results

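Transcripts of the anaerobic, cellulose-degrading bacterium Ruminiclostridium cellulolyticum H10 were counted per coding sequence by RNA sequencing after growth on substrates that contained lignin or did not. There were 5 groups of 3 cultures: cellobiose, the soluble disaccharide of cellulose; Sigmacell cellulose; a mix of Sigmacell cellulose, insoluble wheat arabinoxylan and xyloglucan; and chopped wheat straw, a lignified plant material, collected at the middle and at the end of exponential growth. The 3 other substrates were sampled at the end of exponential growth, so that phase was compared on straw alone. Cellobiose and cellulose were given at 4 g/L and straw at 5 g/L, and the mix held 2 g/L cellulose, 1.5 g/L arabinoxylan and 0.2 g/L xyloglucan. Libraries held between 10714943 and 20715699 counts over 3444 coding sequences. The totals were 11090637, 19446592 and 15886187 on cellobiose, 12600247, 20715699 and 16411801 on cellulose, and 14181904, 16976728 and 16735539 on the mix. They were 14424050, 10714943 and 16856993 on straw at mid phase and 14766663, 15497797 and 15620605 on straw at end phase. Levels are given as counts scaled to the library total (CPM), as mean ± SD with n = 3 cultures per group. Every adjusted p of a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, fitted to all 15 libraries, and a gene was called at an adjusted p under 0.05.

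The libraries of a group resembled each other to different degrees. Spearman correlations across genes between replicates were 0.996 to 0.997 on cellobiose, 0.989 to 0.994 on straw at mid phase, 0.970 to 0.984 on cellulose and 0.959 to 0.983 on the mix. Among the straw end libraries they ran from 0.882 to 0.995, because replicate 1 stood apart. In that library the median gene was at 96.0 CPM, against 41.5 and 41.8 CPM in replicates 2 and 3, and the 10th percentile was 10.8 CPM against 0.794 and 0.704 CPM. Its abundant transcripts differed less, with a 75th percentile of 209.5 CPM against 168 and 173 CPM. In each comparison the totals of genes called higher and lower, and the sizes of the straw sets, are therefore also given without this library. Other counts are given without it only where stated. Leaving it out was planned for the comparisons of straw at end phase and for the straw sets, and was added for the other comparisons and the gene lists after the data were seen. The common dispersion of the fit was 0.133 with the library and 0.0631 without it. Its TMM factor was 1.90, against at most 1.20 in the other libraries. Fold changes moved as well as the spread: the median log2 fold change of the xyl-doc cluster for straw end versus mix was 4.26 with the library and 4.54 without it.

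**Figure D1:**
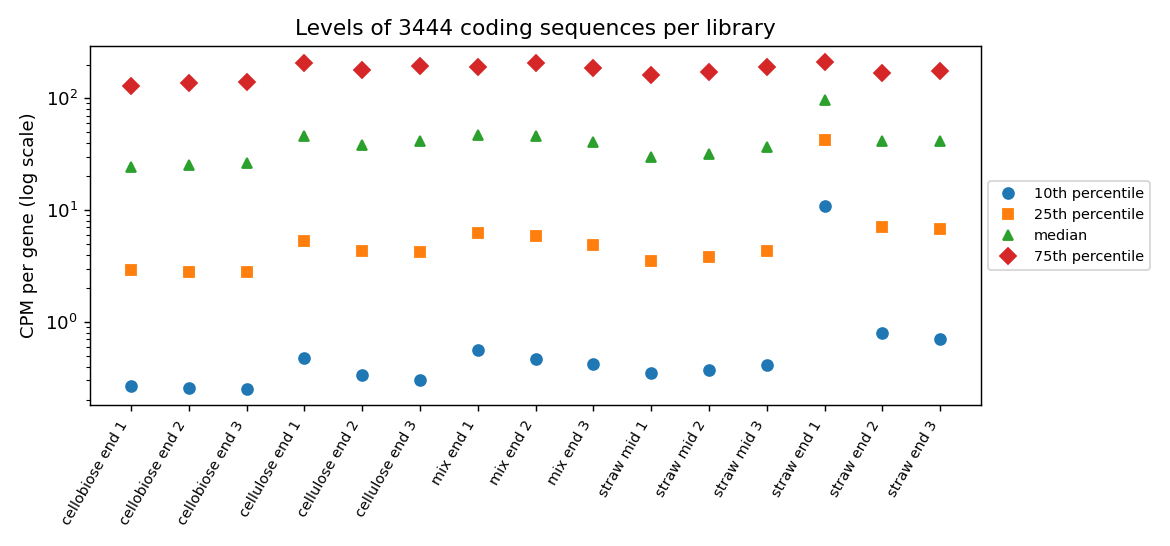
CPM per coding sequence (log scale, y axis) at the 10th, 25th, 50th (median) and 75th percentile in each of the 15 libraries (x axis, group and replicate number). Straw end replicate 1 lies above the other libraries at the lower percentiles, with a 10th percentile of 10.8 CPM against at most 0.794 CPM elsewhere.

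Straw was compared with the polysaccharide mix at the end of exponential growth to find genes whose transcripts differ on a lignified substrate. Straw was given at 5 g/L as chopped material, so amount and physical form differed from the mix as well as lignin. The polysaccharide content of the straw is not given here, so its hemicelluloses and other components may also have differed from the mix. The exact point of growth at collection may have differed as well. These cannot be told apart here or in the straw sets below. The xyl-doc cluster, Ccel_1229 to Ccel_1242, which encodes dockerin-bearing enzymes that act on hemicellulose, was higher on straw in all 14 genes. Its median log2 fold change was 4.26, a 19.1-fold difference, and its share of all counts was 2.08% ± 0.329 (SD, n = 3) on straw against 0.0949% ± 0.0154 (SD, n = 3) on the mix. The first gene of the cluster, Ccel_1229, was at 2638 ± 461 CPM on straw and 78.6 ± 37.7 CPM on the mix, a log2 fold change of 5.13 ± 0.45 (SE, adjusted p = 1.06e-06). The cip-cel cluster, Ccel_0728 to Ccel_0740, which encodes the scaffoldin and major cellulases of the cellulosome, had 12 genes in the table and was higher on straw in 11 of them. Its median log2 fold change was 1.70, a 3.24-fold difference, and the remaining gene, Ccel_0730, had a log2 fold change of 1.25 ± 0.56 (SE, adjusted p = 0.0801). All 12 passed when adjusted over the list alone or without straw end replicate 1. Outside these clusters, Ccel_0150 was higher on straw, at 3029 ± 694 CPM against 49.9 ± 39.0 CPM, a log2 fold change of 6.06 ± 0.72 (SE, adjusted p = 1.28e-05). Ccel_1997 was at 540 ± 87.4 CPM on straw and 3683 ± 1149 CPM on the mix, a log2 fold change of -2.71 ± 0.39 (SE, adjusted p = 7.79e-05). Ccel_1770 was at 175 ± 41.9 CPM against 957 ± 396 CPM, a log2 fold change of -2.49 ± 0.32 (SE, adjusted p = 2.79e-05). The other gene that the naming rule took among those higher on straw, Ccel_2570, rested on straw end replicate 1, where it had 1911 counts against 20 and 12 in replicates 2 and 3. Its log2 fold change was 5.49 ± 1.28 (SE, adjusted p = 0.00432) with that library and 1.11 ± 0.43 (SE, adjusted p = 0.0620) without it.

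In this comparison 858 genes were higher on straw and 477 lower among 3156 tested. Without straw end replicate 1 the counts were 657 and 359, and 582 and 283 genes were called in both fits. Tested as a list against the other genes (camera), the xyl-doc cluster had adjusted p = 0.00796 with an estimated correlation and the cip-cel cluster adjusted p = 0.351 with an estimated correlation. The number of genes lower on straw was 269 without mix replicate 2 and 235 without mix replicate 3. A fit of these 6 libraries alone called 277 genes higher and 69 lower.

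**Figure D2:**
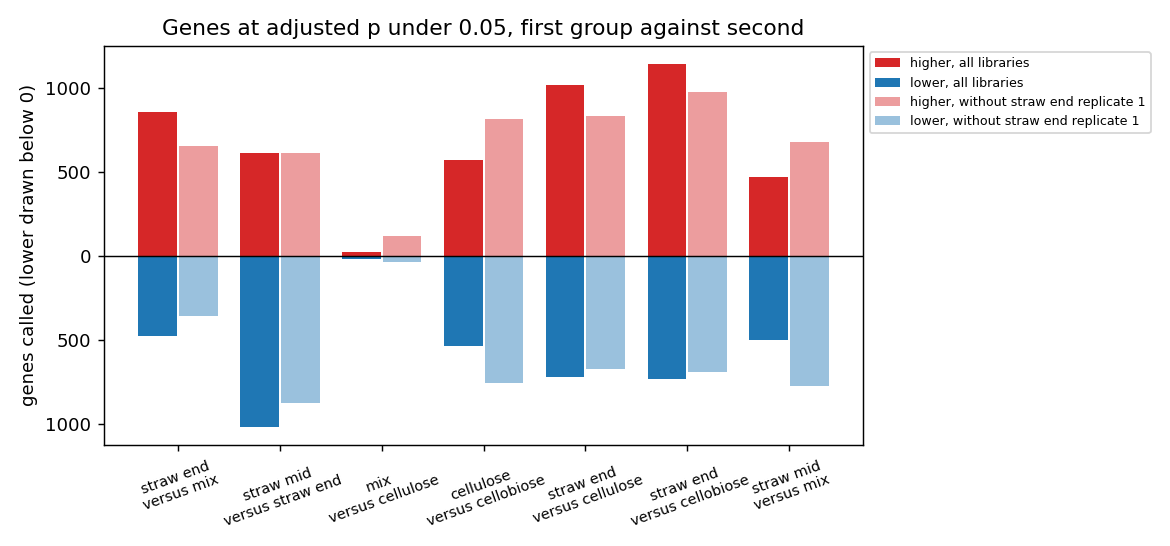
Number of genes called (y axis) higher in the first group, above 0, or lower, below 0, at an adjusted p under 0.05 in the 7 comparisons (x axis). Full bars use all 15 libraries and pale bars leave out straw end replicate 1; the bars for mix versus cellulose, 25 and 15 genes in the full fit, are the shortest.

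The phases of growth on straw were compared to see which transcripts differ between the middle and the end of exponential growth on the lignified substrate. The measured genes of both enzyme clusters were called lower at mid phase, but neither cluster passed as a list, with adjusted p = 0.334 for the cip-cel and 0.0670 for the xyl-doc cluster (camera with an estimated correlation). The estimated correlations were 0.983 and 0.804, so the genes of a cluster moved together and are not independent. At such correlations a list holds little more than a single gene in this test. The 12 measured genes of the cip-cel cluster were all called lower, with a median log2 fold change of -2.09, a 4.25-fold difference, and adjusted p from 0.00191 to 0.0390. The cluster held 3.04% ± 0.437 (SD, n = 3) of counts at mid phase and 12.8% ± 1.85 (SD, n = 3) at end phase. All 14 genes of the xyl-doc cluster were lower at mid phase, with a median log2 fold change of -2.92, a 7.58-fold difference, and the cluster held 0.212% ± 0.0403 (SD, n = 3) of counts against 2.08% ± 0.329 (SD, n = 3). Ccel_2917 was at 1.11 ± 0.784 CPM at mid phase and 499 ± 102 CPM at end phase, a log2 fold change of -8.42 ± 0.79 (SE, adjusted p = 1.16e-06). Ccel_3404 was at 2.01 ± 0.612 CPM against 411 ± 72.4 CPM, a log2 fold change of -7.32 ± 0.58 (SE, adjusted p = 3.51e-07). Higher at mid phase were Ccel_1998, at 744 ± 322 CPM against 79.1 ± 4.81 CPM (log2 fold change 3.54 ± 0.48, SE, adjusted p = 4.81e-05), and Ccel_1995, at 874 ± 182 CPM against 136 ± 32.1 CPM (log2 fold change 2.98 ± 0.45, SE, adjusted p = 0.000125).

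At mid phase 612 genes were higher and 1017 lower than at end phase. Without straw end replicate 1 the counts were 612 and 876, with 509 and 738 called in both fits. The list test of the xyl-doc cluster passed without straw end replicate 1 (adjusted p = 0.0215 with an estimated correlation). Of the called genes 37.6% were higher at mid phase with TMM scaling and 22.7% with total-count scaling, and a fit of the 6 libraries alone called 607 genes lower.

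The mix was compared with cellulose to see the effect of hemicelluloses in the absence of lignin. Cellulose was at 2 g/L in the mix and 4 g/L alone, so the amount of cellulose differed as well as the hemicelluloses. Few genes were called, 25 higher and 15 lower on the mix, and 438 genes had an unadjusted p under 0.05. Ccel_2609 was at 28.6 ± 8.89 CPM on the mix and 262 ± 212 CPM on cellulose, a log2 fold change of -3.19 ± 0.44 (SE, adjusted p = 0.00206). Its neighbour in locus-tag order, Ccel_2608, was at 58.9 ± 13.3 CPM against 529 ± 390 CPM, a log2 fold change of -3.17 ± 0.36 (SE, adjusted p = 0.000304). Both were highest in cellulose replicate 1, where Ccel_2609 was at 507 CPM against 147 and 133 CPM in replicates 2 and 3, and without that library their log2 fold changes were -2.39 and -2.47, with both still called. Ccel_2458 was higher on the mix, at 35.8 ± 25.9 CPM against 7.63 ± 1.63 CPM (log2 fold change 2.18 ± 0.43, SE, adjusted p = 0.0195). Ccel_1223 was also higher, at 170 ± 81.0 CPM against 39.4 ± 7.56 CPM (log2 fold change 2.05 ± 0.38, SE, adjusted p = 0.0149). None of the 12 cip-cel genes was called over all genes tested, with a median log2 fold change of 1.56, whereas 12 passed when adjusted over the list alone. The share of counts of this cluster varied widely between cultures, at 7.07%, 5.22% and 1.92% on the mix and 1.84%, 0.603% and 3.06% on cellulose. Of the 14 xyl-doc genes, with a median log2 fold change of 0.51, 0 were called by edgeR over all genes, 3 passed when adjusted over the list alone, and 3 were called with total-count scaling. The fit without straw end replicate 1 called Ccel_1229 and Ccel_1231 higher (adjusted p = 0.0241 and 0.0460).

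As lists, the cip-cel cluster had adjusted p = 0.131 and the xyl-doc cluster adjusted p = 0.175 with an estimated correlation. The calls depended on single libraries, with 2 higher and 4 lower without mix replicate 2, 5 and 7 without cellulose replicate 2, 130 higher without mix replicate 3, 67 and 27 without cellulose replicate 3, 12 higher without mix replicate 1, 8 lower without cellulose replicate 1, and 122 and 38 without straw end replicate 1. DESeq2 called 155 and 37 genes, the fit of the 6 libraries alone called 0 and 0, and the 4 genes named here did not pass in that fit. Ccel_2458 lost its call without cellulose replicate 2, mix replicate 1 or mix replicate 2, and Ccel_1223 without mix replicate 1 or mix replicate 2. Of the called genes 62.5% were higher on the mix with TMM scaling and 77.5% with total-count scaling, which called 62 genes higher.

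Cellulose was compared with cellobiose, an insoluble polymer against its soluble disaccharide, with no lignin in either. The measured genes of both enzyme clusters were called lower on cellulose, but neither cluster passed as a list (adjusted p = 0.0906 for both, camera with an estimated correlation). The estimated correlations were 0.973 for the cip-cel and 0.786 for the xyl-doc cluster, so here too the genes of a cluster are not independent. All 12 measured cip-cel genes were called lower, with a median log2 fold change of -2.92, a 7.59-fold difference, and adjusted p from 0.000142 to 0.00296. The cluster held 1.83% ± 1.23 (SD, n = 3) of counts on cellulose and 11.2% ± 0.143 (SD, n = 3) on cellobiose. All 14 xyl-doc genes were lower on cellulose, with a median log2 fold change of -2.12, a 4.34-fold difference, at 0.0569% ± 0.0177 (SD, n = 3) of counts against 0.180% ± 0.00729 (SD, n = 3). Ccel_3182 was at 5.17 ± 1.87 CPM on cellulose and 93.5 ± 9.06 CPM on cellobiose, a log2 fold change of -4.74 ± 0.42 (SE, adjusted p = 1.26e-06). Ccel_2368 was at 7.40 ± 6.05 CPM against 122 ± 40.3 CPM, a log2 fold change of -4.67 ± 0.56 (SE, adjusted p = 1.70e-05). Ccel_0437 and Ccel_0435 were higher on cellulose and close to the detection limit on cellobiose. Ccel_0437 had 1082, 7303 and 837 counts on cellulose and 3, 7 and 4 on cellobiose (adjusted p = 0.00225). Ccel_0435 had 372, 1709 and 207 counts on cellulose and 0, 3 and 1 on cellobiose (adjusted p = 0.00370).

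On cellulose 575 genes were higher and 536 lower than on cellobiose. Without straw end replicate 1, which lies outside this comparison and enters through the shared spread, the counts were 814 and 756, and the 575 and 536 genes were all among them. Without cellobiose replicate 1 the number higher was 376. Of the called genes 51.8% were higher on cellulose with TMM scaling and 80.9% with total-count scaling, which shifted the median of all genes by 0.55 on the log2 scale and called 1039 genes higher and 246 lower.

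**Figure D3:**
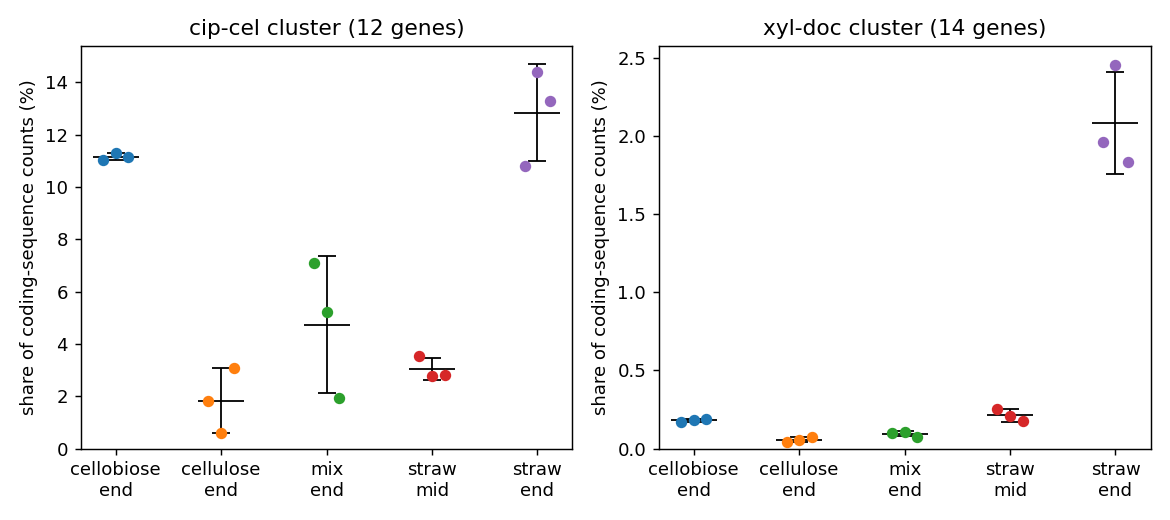
Share of all coding-sequence counts, in percent (y axis), of the cip-cel cluster (left) and the xyl-doc cluster (right) in each library (points) of the 5 groups (x axis), with the mean and SD of 3 cultures. The xyl-doc share was 2.08% at the end of growth on straw and at most 0.212% in the means of the other groups, whereas the cip-cel share was 12.8% on straw at end phase and 11.2% on cellobiose.

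Straw was also compared with cellulose at the end of exponential growth. The 12 measured cip-cel genes were all called higher on straw, with a median log2 fold change of 3.32, a 9.96-fold difference, and the 14 xyl-doc genes were all higher, with a median of 4.76, a 27.1-fold difference. Ccel_1252 was at 5339 ± 1122 CPM on straw and 45.5 ± 15.7 CPM on cellulose, a log2 fold change of 6.94 ± 0.94 (SE, adjusted p = 2.75e-05). Ccel_1229 was at 2638 ± 461 CPM against 26.7 ± 7.26 CPM, a log2 fold change of 6.65 ± 0.48 (SE, adjusted p = 1.08e-07). Ccel_0438 was lower on straw, at 66.1 ± 105 CPM against 743 ± 829 CPM (log2 fold change -4.24, adjusted p = 0.0161), as was Ccel_0437, with a log2 fold change of -4.21 ± 1.37 (SE, adjusted p = 0.0187). Both were variable on cellulose, where Ccel_0438 had 4000, 35182 and 3505 counts, and both lost their calls without cellulose replicate 2, straw end replicate 2 or straw end replicate 3. Without straw end replicate 1 their log2 fold changes were -6.91 and -6.54, and without cellulose replicate 2 they were -2.33 and -2.57.

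On straw 1018 genes were higher and 721 lower than on cellulose, and 837 and 674 without straw end replicate 1, with 773 and 554 called in both fits. As lists, the xyl-doc cluster had adjusted p = 0.0141 and the cip-cel cluster adjusted p = 0.170 with an estimated correlation. A fit of the 6 libraries alone called 637 genes higher and 329 lower.

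Straw and cellobiose were compared at the end of exponential growth as the remaining pair of substrates. The 14 xyl-doc genes were all higher on straw, with a median log2 fold change of 2.90, a 7.44-fold difference. Of the 12 cip-cel genes, 0 were called by edgeR, with log2 fold changes from -1.12 to 1.13, and 4 were called higher with total-count scaling. The gene Ccel_0739 of this cluster was called higher without straw end replicate 1 (log2 fold change 1.46 ± 0.51, SE, adjusted p = 0.0279). Over all 15 libraries the median and mean log2 fold changes of the 12 genes were 0.43 and 0.26, while the camera test gave the direction as down (adjusted p = 0.955 with an estimated correlation) and fry gave it as up (adjusted p = 0.778). Ccel_0143 had 2465, 3322 and 3931 counts on straw and 1, 3 and 7 on cellobiose (adjusted p = 7.82e-06). Ccel_2917 was at 499 ± 102 CPM on straw and 0.847 ± 0.201 CPM on cellobiose, a log2 fold change of 8.59 ± 0.79 (SE, adjusted p = 5.35e-07). Ccel_1870 was lower on straw, at 56.5 ± 7.79 CPM against 974 ± 62.6 CPM (log2 fold change -4.71 ± 0.32, SE, adjusted p = 3.92e-08), as was Ccel_3263, at 35.9 ± 11.6 CPM against 360 ± 55.8 CPM (log2 fold change -3.99 ± 0.40, SE, adjusted p = 1.01e-06).

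On straw 1144 genes were higher and 734 lower than on cellobiose. Without straw end replicate 1 the counts were 980 and 691, with 883 and 609 called in both fits and 1 gene called with opposite signs. The xyl-doc cluster had adjusted p = 0.129 as a list with an estimated correlation. Of the called genes 60.9% were higher on straw with TMM scaling and 82.4% with total-count scaling, which shifted the median of all genes by 0.71 on the log2 scale and called 346 genes lower.

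**Figure D4:**
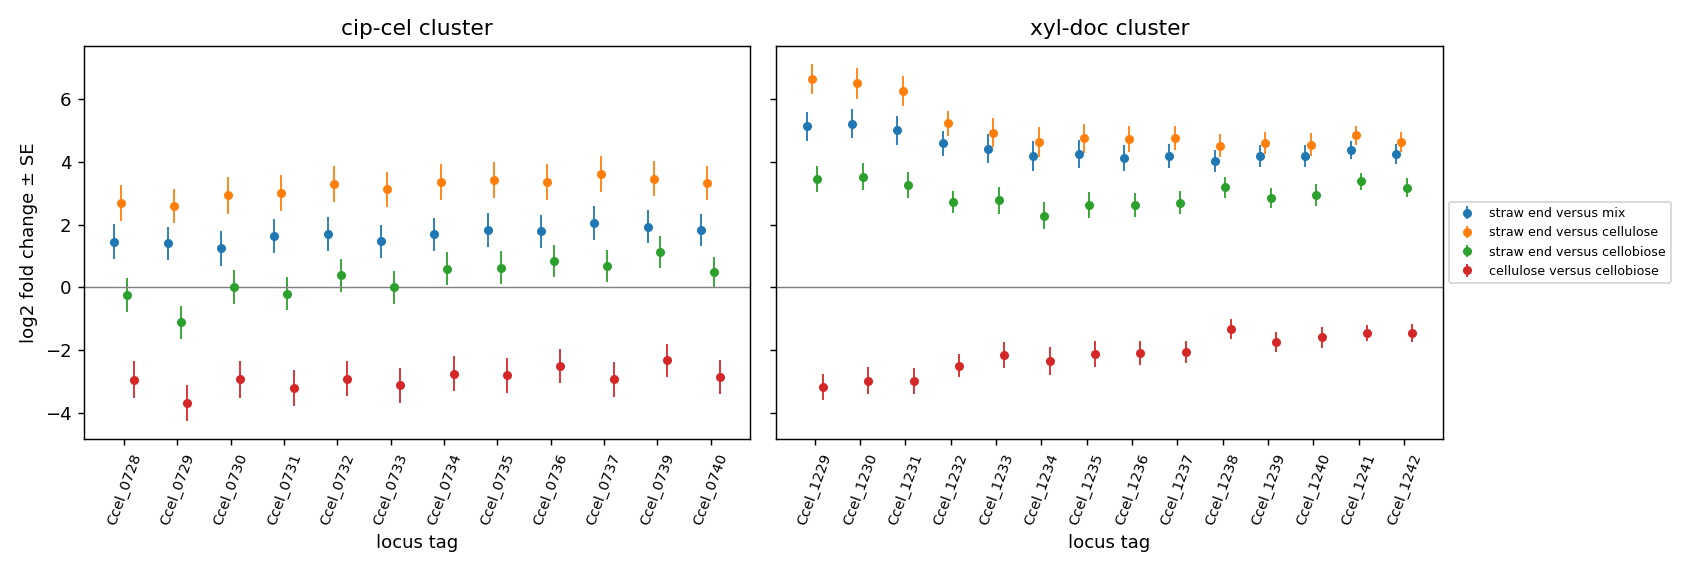
Log2 fold change ± SE (y axis) of each measured gene of the cip-cel cluster (left) and the xyl-doc cluster (right), in locus-tag order (x axis), in 4 comparisons. The xyl-doc genes lie between 4.02 and 5.22 for straw end versus mix, and the cip-cel genes between -1.12 and 1.13 for straw end versus cellobiose.

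Genes at least 2-fold higher on straw at end phase than on each of cellobiose, cellulose and the mix, and called in all 3 comparisons, formed a straw-raised set of 564 genes. All 14 xyl-doc genes and none of the cip-cel genes were in it. Of the 564 genes, 466 were also called higher at end phase than at mid phase on straw, as were 1017 of the 3156 genes tested. These 466 genes were thus called for phase as well as for substrate. However, that comparison uses the same straw end libraries, by whose high levels the set was chosen, so part of the overlap is built in. The 466 were not counted without straw end replicate 1. Ccel_2570 had the largest minimum log2 fold change of the set, 5.49, and rested on straw end replicate 1 as described above. Ccel_1060 was next among members with a mean of at least 20 CPM over the 2 groups and no overlap between replicates in each comparison. Its minimum was 5.24, at 13308 ± 1975 CPM on straw at end phase and 3973 ± 31.8 CPM at mid phase, against 377 ± 216 CPM on the mix, 139 ± 5.69 CPM on cellobiose and a mean of 166 CPM on cellulose. Without straw end replicate 1 the set held 371 genes, of which 334 were in both sets. A straw-lowered set formed in the same way held 98 genes, 58 without straw end replicate 1, 50 without mix replicate 3, 181 without straw end replicate 3 and 46 with total-count scaling, and 43 genes were in both the full set and that without straw end replicate 1.

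The 3 comparisons share the straw libraries. In 20 simulated draws with no difference between groups the straw-raised set held 0 genes, and independent lists of the observed sizes would share 72.5 genes in the raised and 4.11 in the lowered direction. The simulation leaves out the effects of substrate and the product leaves out the shared libraries, so that part of the overlap may come from the shared libraries.

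Straw at mid phase was compared with the mix at end phase as a secondary comparison in which substrate and phase both differ. Of the 14 xyl-doc genes 12 were called higher on straw, with a median log2 fold change of 1.53, a 2.89-fold difference, and 14 passed when adjusted over the list alone or without straw end replicate 1. None of the 12 cip-cel genes was called, with a median log2 fold change of -0.29, and 2 were called lower with total-count scaling. Of the 564 straw-raised genes 106 were also higher at mid phase, against 84.3 for independent lists of these sizes. In the fit without straw end replicate 1, 114 of the 334 genes in both sets were higher at mid phase than on the mix. That fit called more genes higher for straw mid versus mix, 680 against 472, and no value for independent lists was computed for it. The set and this comparison share the mix libraries, so that part of the overlap may come from them. In all 472 genes were higher and 502 lower, and 680 and 774 without straw end replicate 1. Without straw mid replicate 1 or straw mid replicate 2 the number lower was 307 or 303. As lists, the xyl-doc cluster had adjusted p = 0.224 and the cip-cel cluster adjusted p = 0.868 with an estimated correlation. Of the called genes 48.5% were higher on straw with TMM scaling and 27.6% with total-count scaling, which called 286 genes higher.

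The 4 genes Ccel_2109 to Ccel_2112, fixed as a list for cellodextrin uptake and phosphorolysis, were too few for a list test, and 1 of them, Ccel_2109, was called in 3 of the 7 comparisons. It was higher on straw at mid phase than at end phase (log2 fold change 1.30 ± 0.31, SE, adjusted p = 0.00338). It was lower on straw at end phase than on cellulose (-0.82 ± 0.31, SE, adjusted p = 0.0342) and than on cellobiose (-0.78 ± 0.31, SE, adjusted p = 0.0387), but not when adjusted over the list alone, nor without straw end replicate 1. The other 3 genes were called in none of the 7 comparisons of all 15 libraries. In the fit without straw end replicate 1, Ccel_2109, Ccel_2110 and Ccel_2112 were called higher for straw mid versus mix (adjusted p = 0.00674, 0.0203 and 0.0174) and Ccel_2112 for straw end versus mix (adjusted p = 0.0397). Ccel_2109 then stayed higher at mid phase than at end phase (adjusted p = 0.00197), and Ccel_2111 was called lower (adjusted p = 0.0374).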

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

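No gene named by the fixed rule for a comparison changed its direction in it under the alternatives, in which Ccel_1060, named from the straw-raised set, was not followed. In contrast, Ccel_2110, Ccel_2111 and Ccel_2112, not called for straw end versus cellulose, went from negative to positive log2 fold changes in that comparison without straw end replicate 1. The cause of each change below was not tested unless the setting itself removes libraries. RLE size factors and both filters on low counts kept every count of called genes within 1.5 times and every list on its side of the threshold where run. The balance of calls turned for straw mid versus mix, from 472 higher and 502 lower to 491 and 473 with RLE size factors, 578 and 564 with DESeq2 and 546 and 446 without the most abundant genes, and for cellulose versus cellobiose, from 575 and 536 to 541 and 594 without the most abundant genes. It also turned without single libraries in these comparisons and in mix versus cellulose. Total-count scaling gave 62 genes higher for mix versus cellulose, 1039 higher and 246 lower for cellulose versus cellobiose, 346 lower for straw end versus cellobiose, 286 higher for straw mid versus mix, and 46 straw-lowered genes. It shifted the median log2 fold change of all genes by up to 0.71. DESeq2 called 155 genes higher and 37 lower for mix versus cellulose. Fits of the 2 groups compared, with fewer libraries to estimate the spread, gave 277 higher and 69 lower for straw end versus mix, 607 lower for straw mid versus straw end, 0 higher and 0 lower for mix versus cellulose, and 637 higher and 329 lower for straw end versus cellulose. Removing the most abundant genes gave 69 higher for mix versus cellulose. The straw-lowered set held 228 genes at a 1.5-fold and 3 at a 4-fold threshold.

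The replicate numbers did not pair the samples throughout. In none of the 7 comparisons did all 3 same-numbered pairs deviate together with a correlation over 0.1, and at most 2 of the 3 libraries of a first group correlated best with their own number. For mix versus cellulose the correlations were 0.596, 0.0348 and 0.246 for numbers 1, 2 and 3, so a partial pairing there is not excluded. The replicate block gave 40 genes higher for mix versus cellulose, against 25, and moved no other count of called genes by over 1.5 times.

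The list tests depended on the correlation assumed between genes. With a preset correlation, the cip-cel cluster had adjusted p = 0.00150 for straw end versus mix, 0.000949 for straw mid versus straw end, 4.57e-11 for mix versus cellulose, 1.41e-09 for cellulose versus cellobiose and 1.67e-06 for straw end versus cellulose. The xyl-doc cluster had 1.36e-14 for straw mid versus straw end, 5.84e-06 for mix versus cellulose and 1.65e-11 for cellulose versus cellobiose. With an estimated correlation, the calls that held were those of the xyl-doc cluster for straw end versus mix and versus cellulose. With fry, the cip-cel cluster had 0.0185 for straw end versus mix, 0.0137 for straw mid versus straw end, 0.000323 for cellulose versus cellobiose and 0.000412 for straw end versus cellulose, and the xyl-doc cluster 5.37e-05 for straw mid versus straw end and 0.000158 for cellulose versus cellobiose.

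With 1 library left out at a time, straw end replicate 1 included, the number higher ran from 2 to 130 for mix versus cellulose and from 376 to 814 for cellulose versus cellobiose. The number lower ran from 4 to 38 for mix versus cellulose, from 235 to 558 for straw end versus mix and from 303 to 774 for straw mid versus mix. The straw-raised set ran from 371 to 718 genes and the straw-lowered set from 50 to 181, and the xyl-doc list had adjusted p = 0.0215 for straw mid versus straw end without straw end replicate 1. Depth limits the fold of genes with a few counts in a group, such as Ccel_0435 and Ccel_0143 on cellobiose.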

Other observations

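In this part, the tests of an even background by silent genes, of mixing, of an additive background and of a common fold were chosen after the straw end libraries had been seen, the size of a background in the mix libraries was tested after their values had been seen, and the order of genes was examined after the gene calls. Genes that differed between substrates often lay next to each other in locus-tag order. The longest run of straw-raised genes, Ccel_1223 to Ccel_1248, held 26 genes and included the xyl-doc cluster. From cellobiose to cellulose, 21 genes in a row between Ccel_3055 and Ccel_3078 were at least 2-fold higher and 15 from Ccel_3250 to Ccel_3264 at least 2-fold lower. From the mix to straw, 11 genes from Ccel_0459 to Ccel_0469 were at least 2-fold lower, and between the phases on straw 14 genes from Ccel_0765 to Ccel_0778 were at least 2-fold higher at mid phase.

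Of the straw-raised genes with a locus tag, 54.0% were followed by another straw-raised gene, against a mean of 17.7% and a highest value of 23.8% in 10000 shuffled orders (permutation p = 0.0001, the smallest they can give). Among genes in the set both with and without straw end replicate 1 the value was 49.7%, against a highest shuffled value of 16.5%. A candidate explanation is that neighbouring genes are transcribed together. Unstranded counting across gene borders was not tested and stays open.

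Straw end replicate 1 held low-count genes far above every other library, and no biological explanation was tested against the groups, since the pattern lies in 1 library. Of 307 genes at or under 1 CPM in the 14 other libraries, 148 were at least 3 CPM above all of them (48.2%, 95% Wilson interval 42.7 to 53.8%, which spans the bound of 50%). No other library had such a gene, but for those libraries the rule left only 128 or 129 genes. Straw end replicate 1 was then among the 14 others, so these counts of 0 cannot be set beside the 148. The size of an even background over all genes did not decide. At the median level of the silent genes it would hold 0.980% of counts, whereas abundant genes had lost 17.5%, a ratio of 17.8. However, 128 genes were at or under 1 CPM in straw end replicate 1 as well as in the other libraries. They lower both that median and the share of 48.2%. On cellobiose, cellulose, the mix and straw at mid phase they had a median of 0 CPM and a mean of at most 0.00558 CPM. They thus received almost no reads there, and the share does not decide either. Whether those rows can receive reads was not tested, and detected genes rose by more, as given below. Mixing with another library of this series was first tested by the median level of the silent genes, 2.84 CPM, which lay between the bounds of 1 and 3 CPM, and was then tested by the 148 genes above, which such a mixture cannot produce. One common fold rise of low-count genes is argued against by the median folds in 4 classes of level from 1 to 100 CPM in replicates 2 and 3 (a ratio of 10.8). A background added to detected genes stays open. Median differences were between 30.3 and 39.7 CPM over these 4 classes (a ratio of 1.31), but the classes were chosen after the values were seen, and the 610 genes at 100 to 300 CPM rose by 20.4 CPM (a ratio of 1.95 over 5 classes, between the bounds), while the 383 genes under 1 CPM rose by 4.27 CPM and medians above 300 CPM were lower. Transcription of these genes by operon also stays open: neighbouring genes at 1 to 10 CPM correlated with r = 0.401 across 186 pairs, just past the bound of 0.4 set in advance, but with a 95% interval of 0.273 to 0.515, and reading this as undecided was chosen after the value was seen. The same pairs gave 0.386 to 0.480 on cellobiose and cellulose, 0.305 to 0.461 on the mix and 0.239 to 0.301 on straw at mid phase. Such a value is therefore also found in libraries without the pattern. They gave 0.118 and 0.159 in replicates 2 and 3. The pairs were chosen by the level of their genes in those replicates, which narrows the range there, so these values cannot be set beside the others.

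The mix cultures differed among themselves in the cip-cel cluster, from 1.92% to 7.07% of counts. Across 3182 genes, the difference between the mix libraries with the highest and the lowest share correlated with the difference between end and mid phase on straw, taken from replicates 2 and 3 at end phase (r = 0.352, 0.343 without the cip-cel genes, and 0.319 with replicate 1 included), whereas the same comparison gave 0.0847 on cellulose and 0.0927 on cellobiose. Spearman correlations were 0.367 on the mix, 0.203 on cellulose and 0.140 on cellobiose. The SD of the log2 difference was 0.842, 0.556 and 0.313 in these groups. Libraries differed less on cellulose and cellobiose, so the lower correlations there do not single out the mix. Mix cultures collected at different points of growth stay a hypothesis, since the pair of libraries was picked by the cip-cel share and genes are not independent replicates. An even background over all genes is argued against by its size. To lower the share from 7.07% to 1.92% it would have to hold 72.9% of counts, or 212 CPM per gene, whereas 438 genes averaging at most 1 CPM over the 12 libraries other than these 2 and straw end replicate 1 had a mean of 0.246 CPM in the mix library with the lowest share (a ratio of 861). In the mix library with the highest share their mean was 0.350 CPM, so these genes were not higher where the share was lowest. The test set in advance, on genes chosen with the mix libraries included, gave a 1.37-fold difference between the 2 (95% bootstrap interval 1.23 to 1.53, which spans the bound of 1.5) and does not decide. Other differences between the cultures were not tested.

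With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of the 6 libraries, the real split called 346 genes for straw end versus mix (highest other split 1), 1190 for straw mid versus straw end (0), 1535 for cellulose versus cellobiose (0), 966 for straw end versus cellulose (0), 1674 for straw end versus cellobiose (0) and 1200 for straw mid versus mix (0), so that 1 split of 10, the real split, was as large in each. For mix versus cellulose the real split called 0 genes with edgeR, as did the others, so that 10 of 10 were as large, with 361 genes at an unadjusted p under 0.05 and 155 and 37 genes called by DESeq2 in all 15 libraries. For the straw-raised set, 1 of 100 splits of the 12 libraries was as large, the real split with 514 genes, and the highest other split gave 0. The other splits mix substrates that differ among themselves, which widens the spread within groups, so this count does not decide.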
